A study of Mus musculus with 3 samples.

How the data were processed

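Dermal cells of abdominal skin from C57BL/6 mice of the genotype Col1a2creERT2; R26H2B EGFP, aged 8 to 12 weeks, were profiled in 3 libraries: non-pregnant (NP), gestation day 16 (dpc16) and day 42 after birth (dpp42). Per the labels, subcutaneous fat was removed, whole skin was held in 0.25% trypsin for 30 min to part epidermis from dermis, and dermal cells were filtered at 40 and 20 µm and loaded on a 10x Chromium with version 2 chemistry. Tamoxifen was given during pregnancy for dpc16 and dpp42. The NP mouse had it for 3 days and was sampled 48 days later. Per the submitters' processing notes, reads were processed with Cell Ranger 2.2.0 on mm10 (GRCm38). The annotation release and cell calling settings are not given in the sources used here. The deposited matrices hold whole UMI counts per gene and barcode, with no normalization by the authors. They list 28693 genes, the EGFP transgene among them, and 6648 barcodes, all with at least 1908 UMIs. Of the gene identifiers, 28416 matched GENCODE release M21 and 277 did not.

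Cells were kept with at least 200 detected genes and at most 10% mitochondrial UMIs. The gene minimum left out 1, 12 and 3 barcodes of NP, dpc16 and dpp42, and the mitochondrial limit 41, 470 and 115, or 3.08, 11.4 and 9.62%. In all 6022 cells remained and 626 barcodes were left out, against 6020 cells stated by the submitters. Scrublet marked 1, 2 and 1 cells, under the 0.5% fixed as its minimum for use, so no doublets were removed. Median detected genes per kept cell were 1266, 1476.5 and 1328.

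The 3 libraries were clustered together with scanpy 1.11.5: counts scaled to 10000 per cell, log1p, 2000 variable genes with the library as batch key, scaling limited at 10, 30 principal components, 15 neighbours and Leiden clustering (igraph 0.11.9) at resolution 1 with 2 iterations and seed 0. No integration across libraries was applied. Clusters were named from 18 marker lists. The list with the highest mean enrichment over the lower-expressing clusters gave the name, with 20 CPM added to both levels. At least 3 of its markers had to be in 10% of the cells at over 1.4 times that level. Names carry "-like" because they rest on markers alone. Clusters 1, 7 and 28, with more markers of another class among their 10 leading genes, were kept out of the classes. Other tools were Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.

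UMIs were summed per library over each class and given as CPM, counts per 1000000 UMIs, with exact Poisson 95% intervals. Ratios of 2 CPMs have exact conditional binomial 95% intervals. Shares of cells have exact Clopper-Pearson 95% intervals. With 1 library per group there was no test and no p-value. A gene was measured with at least 10 CPM in 1 of the 2 libraries and at least 20 UMIs over both. It counted as higher or lower with a ratio of at least 1.5 either way and an interval that excludes 1. Log2 ratios have 0.5 UMI added to each sum, and a library at 0 has a floor of 3 counts. Members of 33 gene lists fixed before the data were examined gave a median log2 ratio and its percentile among 10000 random lists of equal size, matched on expression in 20 bins, as a description of these libraries. Fibroblast-like cells were the main class. Blood endothelial-like, mural-like and macrophage-like cells were to follow with at least 50 cells in each library, which none of them had. Values of blood and lymphatic endothelial-like cells are given only beside those of the main class, and rest on 41 and 19 NP cells.

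Named genes followed a rule fixed before the data were examined: the 10 highest and 10 lowest log2 ratios against NP, and 5 each way for dpp42 over dpc16, among measured genes of at least 50 CPM in 1 library. Mitochondrial, ribosomal protein, haemoglobin and predicted genes were not ranked. Genes under 0.2 times their CPM in another class of the same library, which free RNA could supply, were not ranked either: 162 in dpc16 over NP, 173 in dpp42 over NP and 192 in dpp42 over dpc16. The rule adds Sfrp1, Igfbp2 and up to 4 members of each list. The list members given in the text were chosen from that set after their values were seen, as were keratinocyte-like clusters 4 and 9. Proliferation was read from 2 or more genes of a fixed list after thinning each cell to 1000 UMIs.

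Intervals and calls were tested on simulated data, drawn at the depths of the fibroblast-like class sums. In these, the 95% intervals held the true ratio for 96.4, 96.3 and 96.4% of genes in dpc16 over NP, dpp42 over NP and dpp42 over dpc16. Of genes with a true change of 2-fold, 58.3, 72.7 and 57.1% were called, and of those with 4-fold 93.6, 97.6 and 76.0%. Of unchanged genes, 3.21, 3.26 and 3.09% were called. The counts were independent Poisson draws from a pooled profile, the model behind the intervals, so coverage near 95% was built in. Differences between cells, clusters or mice were not simulated, so these shares are not error rates for the real libraries. Limits of a first version of this test, set by guess, were not met at these depths and were replaced by limits on interval coverage and on direction.

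Alternatives changed the gene, mitochondrial, resolution, clustering, depth, scaling, pseudocount and expression settings one at a time. After the data were seen, 2 more were added: cells without the 5% highest doublet scores, and clusters 2, 19 and 21, with at least 15 cells in each library, weighted equally. The share of cells with EGFP was read apart from the main comparisons. A few genes of the lists and rankings are not reported here.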

Results

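Single-cell RNA profiles were made from the dermis of abdominal skin of C57BL/6 mice at 3 stages. The NP library came from a non-pregnant control, the dpc16 library from gestation day 16, and the dpp42 library from day 42 after birth. The mice carried Col1a2-creERT2, a tamoxifen-activated recombinase under a collagen promoter, and an H2B-EGFP reporter. Each stage was 1 library, so there are no replicates and no test was made. Intervals of shares, CPM and ratios cover counting error only. Intervals of list medians are taken from the ranked values of the member genes, and show spread between genes instead. The deposited matrices held 1330 barcodes and 6031814 UMIs (unique molecular identifiers) for NP, 4122 barcodes and 21679047 UMIs for dpc16, and 1196 barcodes and 5794940 UMIs for dpp42. After a filter on genes and mitochondrial UMIs, 1289, 3652 and 1081 cells remained, against 1289, 3650 and 1081 stated by the submitters. Median UMIs per kept cell were 3119 in NP, 4300.5 in dpc16 and 3252 in dpp42.

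The first question was which cells made up the dermal suspension at each stage. Keratinocyte-like cells were the most frequent class in all 3 libraries whenever clusters were used. Without clustering, each cell took the class with the most marker UMIs relative to that class's mean over all cells. T, NK and innate lymphoid-like cells then came first in NP (27.2 against 23.5%) and dpp42 (23.2 against 19.5%). In clusters the same class held only 0.621% of NP and 0.555% of dpp42 cells, so these shares rest on the rule used. In clusters, the keratinocyte-like share was 78.8% (76.5 to 81.0%) in NP, 44.4% (42.8 to 46.1%) in dpc16 and 67.3% (64.4 to 70%) in dpp42, with exact 95% Clopper-Pearson intervals. Fibroblast-like cells, named from genes such as Col1a1, Dcn and Pdgfra, made up 7.76% (6.36 to 9.36%) in NP, 29.7% (28.2 to 31.2%) in dpc16 and 10.4% (8.61 to 12.3%) in dpp42. The dpc16 share was 3.83 (3.12 to 4.74) times that of NP, and the dpp42 share 1.34 (1.01 to 1.77) times. The last direction turned with at most 5% mitochondrial UMIs, with cells thinned to 1000 UMIs and in clusters made without stress and proliferation genes. Blood endothelial-like cells took 3.18% (2.29 to 4.29%) in NP and 3.50% (2.93 to 4.15%) in dpc16, a ratio of 1.10 (0.770 to 1.61). They took 8.23% (6.66 to 10.0%) in dpp42, which was 2.59 (1.77 to 3.84) times the NP share. Lymphatic endothelial-like cells were 2.62 (1.62 to 4.48) times as frequent in dpc16 as in NP, and 2.13 (1.18 to 3.96) times in dpp42. Macrophage-like cells numbered 12 in NP, 142 in dpc16 and 11 in dpp42, and the dpc16 share was 4.18 (2.32 to 8.27) times that of NP. All of them in NP and dpp42, but only 79 in dpc16, lay in cluster 11, led by the antigen presentation genes Cd74 and H2-Ab1 and the Langerhans cell gene Cd207, so the ratio sets such cells against a mix. Cluster 11 took 0.931% (0.482 to 1.62%) in NP and 2.16% (1.72 to 2.69%) in dpc16. One macrophage-like cluster of 63 cells, led by Ccl8, Ccl4, Pf4 and the complement gene C1qb, held dpc16 cells only.

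Because keratinocyte-like cells can set every other share, the classes were also counted among non-epithelial cells alone. There, fibroblast-like cells made up 48.5% of 206 NP cells, 65.9% of 1644 dpc16 cells and 40.4% of 277 dpp42 cells. Blood endothelial-like cells made up 19.9%, 7.79% and 32.1%. Clusters with more marker genes of another class than of their own among their 10 leading genes were kept out of every class. They held 5.43% (4.26 to 6.81%) of NP, 11.7% (10.6 to 12.8%) of dpc16 and 7.12% (5.66 to 8.82%) of dpp42 cells. By their best list, clusters 1 and 7 were keratinocyte and cluster 28 fibroblast. Haemoglobin genes contested cluster 1, and the mural gene Steap4 cluster 7. Cluster 1 took 1.63, 5.75 and 1.48% of NP, dpc16 and dpp42 cells, and cluster 7 took 3.57, 4.79 and 5.64%. The keratinocyte-like shares leave these cells out, and so does the count of non-epithelial cells. Trypsin parted epidermis from dermis before the dermal cells were filtered at 40 and 20 µm, so shares of kept cells also depend on the epidermis left on the dermis.

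**Figure D1:**
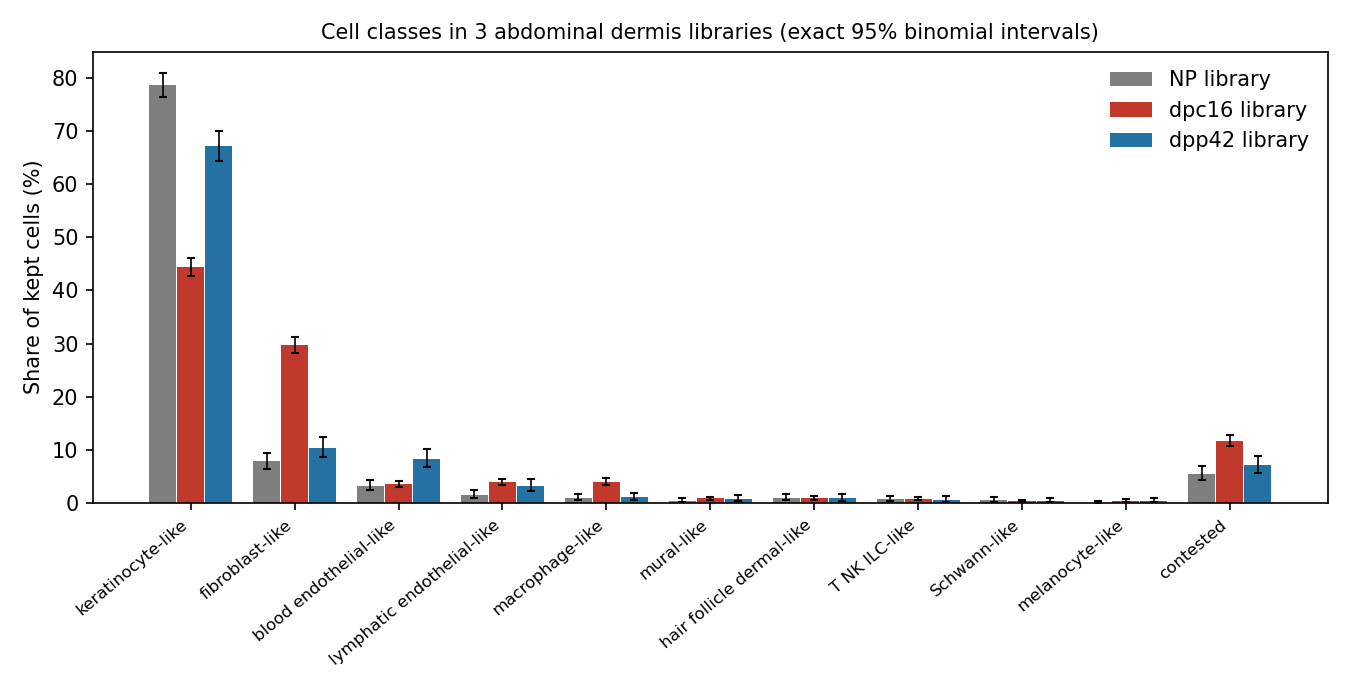
Bars show the share of kept cells (percent, vertical axis) in each cell class (horizontal axis) for the NP, dpc16 and dpp42 libraries, with exact 95% binomial intervals as error bars. The fibroblast-like share reached 29.7% in dpc16, against 7.76% in NP and 10.4% in dpp42.

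Gestation day 16 was then compared with the non-pregnant state within fibroblast-like cells. The dpc16 library was higher in the matrix genes Sparc and Eln and in heat shock genes, and lower in Il6, metallothioneins and Igfbp5. Sparc, which codes for a collagen-binding matrix protein (ENSMUSG00000018593, chromosome 11, 55394500 to 55423183), stood at 25273 against 7216 CPM, a ratio of 3.50-fold (95% interval 3.35 to 3.66). Eln, the elastin gene (ENSMUSG00000029675, chromosome 5, 134702593 to 134747323), stood at 1909.8 against 362 CPM, or 5.28-fold (95% interval 4.34 to 6.49). The cytokine gene Il6 was 6.83-fold (95% interval 5.80 to 8.01) lower and Igfbp5, an insulin-like growth factor binding protein (ENSMUSG00000026185, chromosome 1, 72857932 to 72874884), 5.72-fold (95% interval 5.12 to 6.39) lower. Coordinates are of GRCm38, from GENCODE release M21, and span the whole gene. CPM is UMIs of a gene per 1000000 UMIs summed over the class, which rested on 100 NP, 1084 dpc16 and 112 dpp42 cells. The median log2 ratio over the 8047 measured genes was -0.29, so medians of gene lists fixed before the data were examined stand beside those of random lists matched on expression. Different clusters held most of the class in each library: clusters 2 and 21 in NP, clusters 17, 19 and 25 in dpc16, and clusters 19 and 21 in dpp42. Values are therefore also given with clusters 2, 19 and 21, held by all 3 libraries, weighted equally, and are called matched.

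Of the 10 genes ranked highest in dpc16 over NP, 4 belong to the glandular kallikrein family: Klk1, Klk1b21, Klk1b24 and Klk1b27. These serine protease genes are near-identical copies, so the split of UMIs between them is uncertain. Klk1 (ENSMUSG00000063903, chromosome 7, 44225360 to 44229618) stood at 418 against 3.58 CPM, with 1 NP UMI behind a ratio of 117-fold (95% interval 20.9 to 4609). Klk1b24 stood at 409 against 10.7 CPM. Ctla2a, a cysteine protease inhibitor gene with a close paralog (ENSMUSG00000044258, chromosome 13, 60934155 to 60936625), stood at 5970.2 against 35.8 CPM, or 167-fold (95% interval 90.6 to 348). Mgp, which codes for matrix Gla protein, an inhibitor of calcification (ENSMUSG00000030218, chromosome 6, 136872435 to 136875823), had no UMI in NP and 393 CPM in dpc16, at least 36.6-fold higher against a floor of 3 counts in the NP class sum. Ctla2a and Plac8 lead cluster 25, the 4 kallikreins cluster 17 and Mgp cluster 19. With the shared clusters weighted equally, Mgp stood at 389 against 0 CPM, Klk1 at 97.3 against 2.47 CPM, Klk1b24 at 136 against 7.41 CPM, Stc2 at 25.4 against 2.47 CPM and Ctla2a at 1143 against 78.7 CPM. Pthlh, the gene for parathyroid hormone-related protein, also had no NP UMI and was at least 6.30-fold higher. The phospholipase gene Pla2g2e stood at 133 against 3.58 CPM (37.2-fold, 6.66 to 1473) and the stanniocalcin gene Stc2 at 70.4 against 3.58 CPM (19.7-fold, 3.50 to 779), each with 1 NP UMI. Plac8 stood at 103 against 3.58 CPM (matched 2.65 against 0 CPM), also with 1 NP UMI, and was lower than NP when each library was clustered alone and with at most 5% mitochondrial UMIs. Of the 10 genes ranked highest, 3 were measured in keratinocyte-like cells, and all 3 were higher in dpc16 there too. Free RNA from fibroblast-like cells could give the same direction, so a rise within keratinocyte-like cells is not shown.

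Among the 10 genes ranked lowest, Thbs1, for the matrix protein thrombospondin 1, stood at 181 against 1085 CPM and was 5.98-fold (95% interval 5.23 to 6.82) lower. The leukaemia inhibitory factor gene Lif was 8.60-fold (4.91 to 14.7) lower and the interferon-inducible GTPase gene Gbp2, which leads cluster 2, 5.86-fold (4.57 to 7.46) lower. Scg3, a secretogranin gene (ENSMUSG00000032181, chromosome 9, 75643189 to 75684056), stood at 8.75 against 154 CPM and was 17.6-fold (11.2 to 27.6) lower, and Rhd stood at 1.25 against 50.1 CPM. Chl1 was 9.21-fold (4.57 to 17.8), Zswim4 7.47-fold (4.19 to 12.9) and Fam198b 5.73-fold (3.63 to 8.81) lower. The last members, AY036118 (7.08 against 64.5 CPM) and Zc3h11a (7.08 against 53.7 CPM), were lower in keratinocyte-like cells too, at 7.34 against 57.9 CPM and 6.19 against 32.3 CPM. Of the 5 measured in keratinocyte-like cells, 3 were lower there, with Chl1 at 65.5 against 195 CPM as the third, and 2 higher, Thbs1 at 438 against 224 CPM and Zswim4 at 19.4 against 12.9 CPM. Matched log2 ratios were -1.28 for Gbp2, -2.02 for Lif, -1.84 for Fam198b, -4.40 for Rhd and -3.94 for AY036118, against -2.56, -3.12, -2.54, -5.26 and -3.20 in the class sums.

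The collagen and collagen assembly genes did not move together. Of 24 measured members, 9 were higher, 4 lower and 11 neither, and the list had a median log2 ratio of 0.09, against -0.12 for matched random lists (percentile 89.2). Besides Sparc, the procollagen protease gene Adamts2 stood at 1258 against 415 CPM (3.03-fold, 2.52 to 3.67) and the crosslinking enzyme gene Lox at 244 against 100.3 CPM (2.44-fold, 1.68 to 3.68). The lysyl hydroxylase gene Plod3 was lower, at 25.4 against 57.3 CPM. Of the elastic fibre genes, 4 of 12 were higher and 3 lower. Mfap4 stood at 2090.0 against 433 CPM and Mfap2 at 590.1 against 165 CPM, both microfibril-associated protein genes, whereas Ltbp4 was 3.74-fold (3.00 to 4.63) lower. Sparc and Adamts2 lead cluster 17, Eln and Mfap4 cluster 19. With the shared clusters weighted equally, the log2 ratio was 1.80 for Sparc, 2.23 for Eln and 2.46 for Mfap4. Fibroblast transcripts were also more frequent in other classes of the dpc16 library, as free RNA would give: Sparc stood at 257 against 44.2 CPM in keratinocyte-like cells. The hyaluronan synthase genes Has1 and Has2 were 3.94-fold (3.29 to 4.69) and 5.31-fold (2.89 to 9.29) lower. In the list of matrix proteases and their inhibitors, 4 of 18 genes were higher, among them cathepsin K (Ctsk, 1445 against 344 CPM), and 4 lower.

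The heat shock list stood apart from its random lists. Of its 11 measured members, 9 were higher, 0 lower and 2 neither, with a median log2 ratio of 1.16, against -0.09 for matched random lists (percentile 100). Hspa1a, an inducible Hsp70 gene, stood at 4071 against 1389 CPM, Hspb1 at 1127 against 351 CPM and Hsp90aa1 at 2089.6 against 769.9 CPM. Heat shock genes were higher in other dpc16 cells as well: Hspa1a stood at 2993 against 784 CPM in keratinocyte-like and 3648 against 959 CPM in lymphatic endothelial-like cells. Immediate early genes had a median log2 ratio of 0.03, against -0.11 for matched random lists (percentile 76.4); Jun was higher (903 against 347 CPM), as was Klf2 (175 against 64.5 CPM), while Zfp36 (769 against 1529 CPM) and Nr4a2 (27.5 against 75.2 CPM) were lower. Nr4a2 was higher with at most 5% mitochondrial UMIs.

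Chemokine and inflammatory genes were lower in most members. Of 17 measured members, 4 were higher, 9 lower and 4 neither, with a median log2 ratio of -0.93, against -0.21 for matched random lists (percentile 0.09). The interval of the median, -1.31 to 0.21, spans 0. Besides Il6 and Lif, the thymic stromal lymphopoietin gene Tslp was 5.29-fold (2.52 to 10.3) lower. Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453) and Ccl7, monocyte-attracting chemokine genes that lead cluster 2, stood at 1975 against 4748 CPM and 1905 against 4727 CPM. The cyclooxygenase gene Ptgs2 stood at 21.5 against 96.7 CPM. In matched clusters the log2 ratio was -1.98 for Il6 and -2.65 for Ptgs2, but -0.08 for Ccl2 and -0.37 for Ccl7, and the list median was -0.37. Cxcl13, at 0 in NP and 45 CPM in dpc16, was among the 4 higher genes, a direction that reversed with that weighting and with at most 5% mitochondrial UMIs.

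In the lipid and adipogenic list, 5 of 7 measured genes were higher, with a median log2 ratio of 1.96, against -0.26 for matched random lists (percentile 100), but the interval of the median, -0.79 to 4.05, spans 0. Higher values were not limited to fibroblast-like cells: 5 of 7 were higher in blood endothelial-like cells (median 0.97), and in keratinocyte-like cells Lpl stood at 135 against 34.7 CPM and Apoe at 10720 against 4536 CPM. The mix of keratinocyte-like clusters differed, however. Clusters 4 and 9 held 217 and 268 of 1016 NP cells but 165 and 100 of 1623 dpc16 cells. Cluster 8, with Plin2 among its leading genes, held 62 and 202. No matched values were made for this class, so mix and expression cannot be told apart in its sums. Lipoprotein lipase (Lpl) stood at 192 against 14.3 CPM (13.4-fold, 5.22 to 49.3) and apolipoprotein E (Apoe) at 4033 against 788 CPM (5.12-fold, 4.48 to 5.87). Plin2, for a lipid droplet protein, stood at 90.2 against 21.5 CPM, a level that free RNA could give, since keratinocyte-like cells stood at 569.7 against 295 CPM. Lpl had a matched log2 ratio of 2.18. Apoe and Plin2 were lower than NP at clustering resolution 2. The reticular fibroblast list, which holds Mgp and Plac8, had 5 of 8 genes higher, and its member Gpx3, which leads cluster 25, stood at 1328 against 433 CPM, with a matched log2 ratio of 0.87. In the secretory pathway list, 9 of 21 genes were lower and none higher, with a median log2 ratio of -0.59, against -0.19 for matched random lists (percentile 2.11). The endoplasmic reticulum chaperone genes Hspa5 and Hsp90b1 were 2.38-fold (2.12 to 2.66) and 2.54-fold (2.23 to 2.89) lower. Of the hormone receptor genes, 6 of 10 were lower and 1 higher, with a median log2 ratio of -0.93, against -0.29 for matched random lists (percentile 1.34). The interval of that median, -1.87 to 0.47, spans 0. The relaxin receptor gene Rxfp1 stood at 3.75 against 28.6 CPM, the oxytocin receptor gene Oxtr at 24.6 against 68.0 CPM and the prolactin receptor gene Prlr at 11.2 against 28.6 CPM, each from fewer than 20 NP UMIs. Matched values of Prlr were 9.23 against 7.41 CPM, short of the size rule. In the hypoxia and glycolysis list, 5 of 16 genes were lower, including Vegfa (23.7 against 89.5 CPM), and none higher.

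The insulin-like growth factor list went both ways, with 4 higher and 2 lower of 12. Igfbp7 stood at 2000.4 against 691 CPM, and Igfbp2 (ENSMUSG00000039323, chromosome 1, 72824503 to 72852474) at 688 against 816 CPM, which is short of the size rule of 1.5-fold. The matched Igfbp2 values turn the direction and pass that size, at 1687 against 1044 CPM (log2 0.69). Of the TGF-beta and BMP genes, 7 of 19 were lower, among them the BMP antagonist gene Grem1 (3.75-fold lower, 2.85 to 4.87), and 2 higher, among them Id1 (57.5 against 10.7 CPM). Of the Wnt genes, 3 of 14 were lower, including Wnt5a (49.6 against 233 CPM) and Wif1 (7.08 against 43.0 CPM), and Sfrp4 was higher (6.63-fold, 1.81 to 55.1). Among matched random lists, the medians of the insulin-like growth factor, TGF-beta and Wnt lists lay at percentiles 49.8, 12.7 and 48.0. None of these lists stood apart. With the median over all measured genes at -0.29, an excess of lower members does not by itself set a list apart. Sfrp1 (ENSMUSG00000031548, chromosome 8, 23411502 to 23449632) stood at 39.4, 40.2 and 40.9 CPM in NP, dpc16 and dpp42, with differences within counting error in these sums. Matched values, which have no interval here, moved apart: Sfrp1 stood at 9.88, 14.7 and 34.9 CPM (log2 1.63 for dpp42 over NP and 1.31 for dpp42 over dpc16). Glucocorticoid-responsive genes split: the metallothionein genes Mt1 and Mt2 stood at 2618 against 15029 CPM and 1491 against 8068 CPM, whereas Tsc22d3 stood at 277 against 75.2 CPM. Mt1 was also lower in blood endothelial-like cells (1215 against 5152 CPM) and keratinocyte-like cells (1207 against 3405 CPM). The matched log2 ratio was -1.84 for Mt1, -1.59 for Mt2 and 3.09 for Id1. All 4 haemoglobin genes were higher in dpc16 fibroblast-like cells, but haemoglobin UMIs were present in 29.2 to 46.2% of cells in each dpc16 class of 10 or more cells, against 2% of NP fibroblast-like cells, so free RNA stays open as the source. In keratinocyte-like cells the shares were 14.7% in NP, 35.2% in dpc16 and 20.4% in dpp42.

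**Figure D2:**
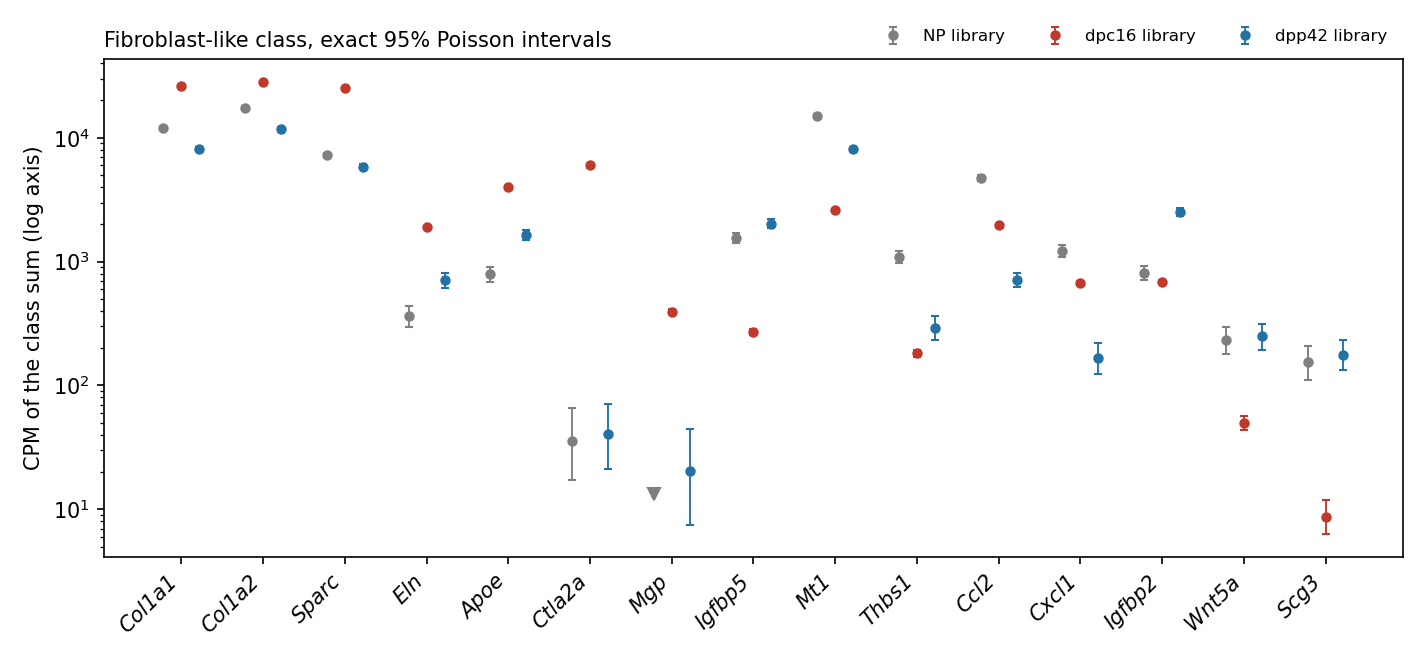
Points show CPM of the fibroblast-like class sum (logarithmic vertical axis) for 15 genes (horizontal axis) in the NP, dpc16 and dpp42 libraries, with exact 95% Poisson intervals, and a triangle marks the upper limit of a library at 0. Sparc stood at 25273 CPM in dpc16 against 7216 in NP and 5848 in dpp42, and Igfbp5 at 269.7, 1543 and 2019.

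**Figure D3:**
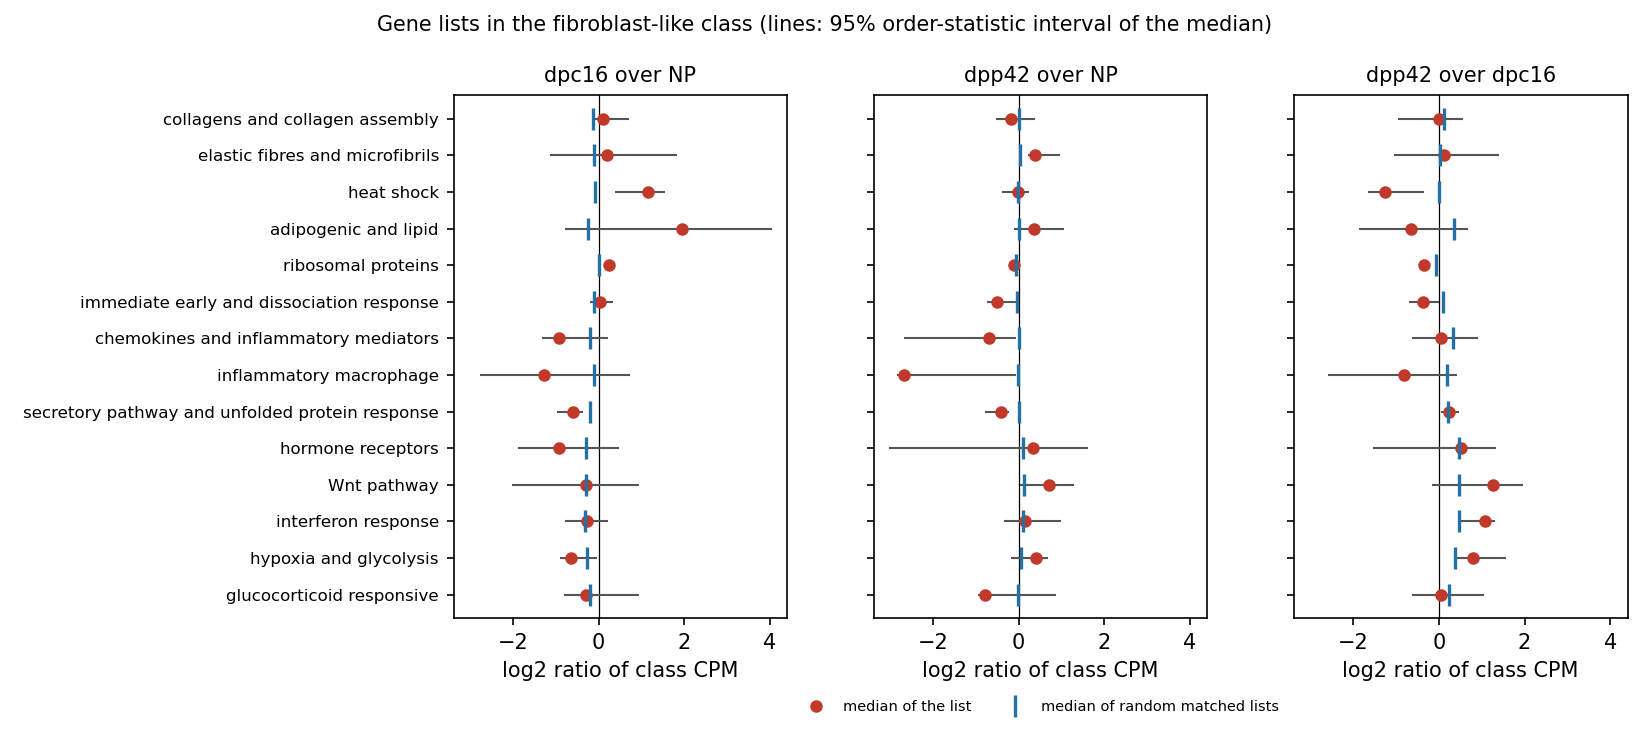
Points show the median log2 ratio (horizontal axes) of 14 gene lists (vertical axis) in fibroblast-like cells for the 3 comparisons, with lines for 95% order-statistic intervals and bars for the median of random matched lists. For the adipogenic list in dpp42 over NP, with 3 measured members, the line runs from the lowest to the highest member. The heat shock median was 1.16 for dpc16 over NP, -0.01 for dpp42 over NP and -1.27 for dpp42 over dpc16.

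Day 42 after birth was likewise compared with the non-pregnant state in fibroblast-like cells. The dpp42 library was lower in chemokine, cyclooxygenase and immediate early genes and in Hmox1, and higher in Igfbp2, in a few matrix genes and in Mmp11. Ccl2 stood at 713 against 4748 CPM, 6.66-fold (95% interval 5.75 to 7.75) lower, and Cxcl1, a neutrophil-attracting chemokine gene, at 167 against 1214 CPM, 7.27-fold (95% interval 5.37 to 10.0) lower. Igfbp2, which leads cluster 21, stood at 2513 against 816 CPM, 3.08-fold (95% interval 2.65 to 3.59) higher. Its matched log2 ratio was 0.82, against 1.62 in the class sums. The median log2 ratio over 3819 measured genes was 0.08. Mitochondrial transcripts had a median log2 ratio of 0.51, against -0.06 for matched random lists (percentile 100), with 4 of 12 higher and none lower.

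Mmp11, the stromelysin 3 gene (ENSMUSG00000000901, chromosome 10, 75923222 to 75936496), had no UMI in NP and 85.2 CPM in dpp42, at least 7.94-fold higher. The activin subunit gene Inhbb stood at 119 against 10.7 CPM (11.1-fold, 3.50 to 56.5) and the stathmin family gene Stmn2 at 184 against 10.7 CPM (17.1-fold, 5.56 to 85.7). Nrep stood at 113 against 14.3 CPM, and Iah1, Mea1, Abca8a and Tspan17 were 6.35 to 9.05 times higher, each from 2 or 3 NP UMIs. The other two, Krt6a and Spink5, are epidermal genes: Krt6a stood at 113 against 3.58 CPM and Spink5 at 81.8 against 7.16 CPM, and in keratinocyte-like cells at 142 against 26.0 CPM and 361 against 341 CPM. Lowest in dpp42 was the haem oxygenase gene Hmox1, at 23.9 against 319 CPM (13.4-fold lower, 6.22 to 34.2). It was lower in blood endothelial-like cells too, at 239 against 430.0 CPM. Transglutaminase 2 (Tgm2) stood at 6.82 against 89.5 CPM, the stress cytokine gene Gdf15 at 20.5 against 132 CPM and Oxtr at 6.82 against 68.0 CPM. Zswim4, Arih2 and Tnip1 were 5.78 to 10.5 times lower, each from 2 to 4 dpp42 UMIs. With the shared clusters weighted equally, the log2 ratio was 3.06 for Stmn2, 4.11 for Nrep, -2.49 for Hmox1, -2.70 for Tgm2 and -1.53 for Tnip1.

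Of the chemokine and inflammatory list's 15 measured members, 3 were higher, 7 lower and 5 neither, with a median log2 ratio of -0.70, against 0.01 for matched random lists (percentile 0.02). Ptgs2 stood at 13.6 against 96.7 CPM and Cxcl2 at 10.2 against 78.8 CPM. The log2 ratio with the shared clusters weighted equally was -1.47 for Ccl2, -1.95 for Cxcl1 and -2.60 for Ptgs2, but -0.10 for Ccl7, and the list median was -0.10. Immediate early genes, which dissociation induces, were lower in 6 and higher in 2 of 18 measured members, with a median log2 ratio of -0.51, against -0.03 for matched random lists (percentile 0.02). Junb stood at 402 against 1078 CPM, Egr1 at 658 against 1393 CPM and Btg2 at 177 against 412 CPM. Klf2 stood at 133 against 64.5 CPM, with the opposite direction when clusters were made without stress and proliferation genes. Free RNA could give this level too, since blood endothelial-like cells stood at 833 against 620.2 CPM. Glucocorticoid-responsive genes had a median log2 ratio of -0.79, against -0.02 for matched random lists (percentile 0.01), but the interval of the median, -0.95 to 0.88, spans 0. Of 9 measured, 5 were lower, including Nfkbia (740.0 against 2009 CPM) and Errfi1 (297 against 569 CPM), while Tsc22d3 stood at 310.3 against 75.2 CPM. Matched log2 ratios were -0.70 for Nfkbia and 1.25 for Tsc22d3, and -0.45 for Errfi1, short of the size rule. Mt2 stood at 4184 against 8068 CPM, a direction that reversed with the shared clusters weighted equally (log2 0.05) or with at most 5% mitochondrial UMIs. In the secretory pathway list 5 of 19 genes were lower and none higher, among them Herpud1 (2.10-fold lower, 1.4 to 3.21), Ddit3 (2.31-fold lower, 1.22 to 4.58) and Dnajb9 (2.10-fold lower, 1.16 to 3.93). Herpud1 was short of the size rule with the shared clusters weighted equally (log2 -0.23).

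No heat shock gene met the size rule in dpp42 over NP, with a list median of -0.01. Most collagen genes did not either (18 of 24), with Plod1 at 71.6 against 28.6 CPM among 4 higher genes, Loxl1 at 133 against 251 CPM and P4ha2 at 58.0 against 118 CPM as the 2 lower ones, and a median log2 ratio of -0.18, against 0.00 for matched random lists (percentile 4.85). The elastic fibre list had a median log2 ratio of 0.37, against 0.02 for matched random lists (percentile 98.2), with Eln at 706 against 362 CPM (1.95-fold, 1.53 to 2.50) and Mfap4 at 1006 against 433 CPM (2.32-fold, 1.87 to 2.89) as its 2 higher members and none lower. Higher values were also found for the matrix genes Postn (501 against 215 CPM), Aspn (576 against 261 CPM), Col15a1 (529 against 258 CPM) and Nid1 (222 against 118 CPM). Among signalling genes, Bmp4 stood at 85.2 against 17.9 CPM, the R-spondin gene Rspo1 at 170.5 against 68.0 CPM and Igfbp7 at 1340.1 against 691 CPM, while Igf1 stood at 71.6 against 179 CPM and Gas6 at 205 against 816 CPM. Rxfp1 stood at 92.1 against 28.6 CPM, reversed with at most 5% mitochondrial UMIs, and Apoe at 1630.0 against 788 CPM, reversed at resolution 2. In the hypoxia and glycolysis list, Ldha (246 against 139.7 CPM) and Pkm (232 against 129 CPM) were higher and Hk2 (51.1 against 132 CPM) was lower, the last reversed with at most 5% mitochondrial UMIs. Matched, the log2 ratio was 1.11 for Bmp4, 0.63 for Plod1, 1.86 for Mfap4, -1.39 for Gas6 and -0.62 for Hk2, while Igf1 (-0.41) and Pkm (0.39) fell short of the size rule.

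The dpp42 library was last set against dpc16, again in fibroblast-like cells. Kallikrein, type I collagen and heat shock genes were lower in dpp42, and several Wnt, interferon-response and hypoxia genes higher. The kallikreins Klk1, Klk1b21, Klk1b24 and Klk1b27 had no UMI in dpp42, and Klk1 was at least 40.8-fold lower. Ctla2a stood at 40.9 against 5970.2 CPM, 146-fold (95% interval 83.5 to 282) lower, and Sparc at 5848 against 25273 CPM, 4.32-fold (95% interval 4.12 to 4.54) lower. The median log2 ratio over 8529 measured genes was 0.50. Mitochondrial transcripts had a median log2 ratio of 0.75, against -0.02 for matched random lists (percentile 99.8), with 10 of 13 higher and none lower. Genes ranked highest were the EGFP transgene (58.0 against 0.833 CPM), Rxfp1 (92.1 against 3.75 CPM), Scg3 (177 against 8.75 CPM), the alanine aminotransferase gene Gpt2 (92.1 against 4.58 CPM) and Spink5 (81.8 against 7.50 CPM). Matched log2 ratios were 3.78 for Rxfp1 and 3.26 for Scg3, and 0.45 for Spink5, short of the size rule.

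Of the collagen list's 24 measured members, 4 were higher, 9 lower and 11 neither, with a median log2 ratio of 0.00, against 0.13 for matched random lists (percentile 24.4). The type I collagen genes Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) and Col1a2 (ENSMUSG00000029661, chromosome 6, 4504814 to 4541544), which lead cluster 17, stood at 8078 against 25972 CPM and 11822 against 28146 CPM, and Adamts2 was 4.19-fold (3.40 to 5.23) lower. With the shared clusters weighted equally, the log2 ratio was -1.61 for Col1a1 and -1.16 for Col1a2. Col1a1 in keratinocyte-like cells stood at 13.6 against 181 CPM. Eln was 2.71-fold (2.36 to 3.12) and Mfap2 2.70-fold (2.11 to 3.52) lower, while Ltbp4 was 4.32-fold (3.52 to 5.26) and Fbln1 3.55-fold (3.00 to 4.19) higher. In the heat shock list 8 of 11 genes were lower and none higher, with a median log2 ratio of -1.27, against 0.01 for matched random lists (percentile 0). Hsp90aa1 was 3.56-fold (3.06 to 4.17) lower, and Hspa1a stood at 1378 against 4071 CPM. Interferon-response genes were higher in 10 and lower in 1 of 22 measured members, with a median log2 ratio of 1.07, against 0.47 for matched random lists (percentile 99.8). Gbp2 was 4.97-fold (3.82 to 6.39), Gbp3 4.09-fold (1.73 to 8.66) and Ifi35 2.42-fold (1.36 to 4.05) higher. Wnt genes had a median log2 ratio of 1.27, against 0.46 for matched random lists (percentile 99.9) and 7 of 14 higher, including Wnt5a (5.02-fold, 3.81 to 6.55) and Wif1 (6.26-fold, 3.03 to 12.2), with Sfrp4 at 0 in dpp42 and at least 4.64-fold lower. The interval of the Wnt median, -0.17 to 1.96, spans 0. Hypoxia and glycolysis genes had 9 of 16 higher and none lower, with a median log2 ratio of 0.80, against 0.37 for matched random lists (percentile 97.5). Vegfa was 3.30-fold (2.01 to 5.20) and Slc2a1, a glucose transporter gene, 3.07-fold (1.32 to 6.32) higher. Bnip3 stood at 116 against 39.6 CPM, reversed in clusters made without stress and proliferation genes and with at most 5% mitochondrial UMIs. Of single genes, Igfbp5 was 7.48-fold (6.78 to 8.25) higher and Igfbp2 3.65-fold (3.37 to 3.96) higher, the latter with a log2 ratio of 0.13 when the shared clusters were weighted equally. Mt1 was 3.09-fold (2.95 to 3.23), Grem1 4.69-fold (3.68 to 5.93) and Hgf, the hepatocyte growth factor gene, 10.3-fold (4.58 to 22.4) higher. The progesterone receptor gene Pgr stood at 6.82 against 59.8 CPM, with 2 dpp42 UMIs, and Igf1 was 4.46-fold (2.90 to 7.22) lower. Matched log2 ratios were -4.16 for Ctla2a, 1.34 for Wnt5a, 1.19 for Fbln1, -1.32 for Pgr and -1.39 for Igf1, and Grem1 stood at 249.9 against 88.6 CPM.

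Proliferation was counted as the share of cells with UMIs of at least 2 genes of the proliferation list after each cell was thinned to 1000 UMIs. No kept cell held fewer than 1000. Keratinocyte-like cells had the same share within counting error at all stages: 9.35% (7.63 to 11.3%) in NP, 9.24% (7.88 to 10.8%) in dpc16 and 9.35% (7.34 to 11.7%) in dpp42. Among fibroblast-like cells the thinned share was 0 of 100 in NP, with an exact upper limit of 3.62%, 0.830% (0.380 to 1.57%) in dpc16, and 0 of 112 in dpp42, with an exact upper limit of 3.24%. Unthinned, these were 0, 4.43 and 0.893% at median depths of 2631.5, 4088.5 and 2420 UMIs. Summed over fibroblast-like cells, list genes stood at 39.4 CPM (19.7 to 70.5) in NP, 142 CPM (131 to 153) in dpc16 and 61.4 CPM (36.4 to 97.0) in dpp42. All kept cells together had thinned shares of 7.68% (6.29 to 9.27%), 5.28% (4.58 to 6.06%) and 6.66% (5.25 to 8.31%). Keratinocyte-like cells carried the list at 824 CPM in dpc16, so free RNA in fibroblast-like cells stays open.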

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

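All 4 tests of the EGFP values were chosen after these values were seen. EGFP, the nuclear reporter switched on by Col1a2-creERT2, ranked among the genes of dpp42 over dpc16, but its share of cells is outside the comparisons above. In fibroblast-like and keratinocyte-like cells, the classes with 100 or more cells in every library, that share lay above NP in 3 class and library pairs. A UMI of EGFP was present in 2.53% (1.82 to 3.41%) of 1623 dpc16 and 1.93% (1.06 to 3.21%) of 727 dpp42 keratinocyte-like cells, against 0.591% (0.217 to 1.28%) of 1016 in NP. The intervals of dpp42 and NP overlap. A few clusters carried these cells: in dpc16 clusters 4, 5 and 10 held 9, 7 and 9 of the 41, at 16.2, 15.1 and 8.49 CPM, and cluster 10, with median depths of 13487 to 20558.5 UMIs, held 8 of 14 in dpp42 and 4 of 6 in NP. In dpp42 fibroblast-like cells it was present in 12.5% (7.01 to 20.1%) of 112, against 12.0% (6.36 to 20.0%) of 100 in NP, a difference within counting error. In dpc16 fibroblast-like cells it was present in 4 of 1084, or 0.369% (0.101 to 0.942%). Among smaller classes, 1 macrophage-like and 1 melanocyte-like cell of dpc16 and 1 hair follicle dermal-like cell of dpp42 had it. No EGFP UMI was found in 60 NP, 269 dpc16 and 123 dpp42 endothelial-like cells. Median UMIs of fibroblast-like cells were 2631.5 in NP, 4088.5 in dpc16 and 2420 in dpp42. With cells thinned to 1000 UMIs, the fibroblast-like shares were 6.00% in NP, 0.0923% in dpc16 and 5.36% in dpp42, and the keratinocyte-like shares 0.0984, 0.555 (0.254 to 1.05) and 0.275%, with 0 of 269 dpc16 endothelial-like cells, an exact upper limit of 1.36%. Per UMI, EGFP in dpc16 stood at 5.81 CPM (4.45 to 7.47) in keratinocyte-like and 0.833 CPM (0.227 to 2.13) in fibroblast-like cells, with median depths of 4967 and 4088.5 UMIs.

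Fibroblast-like cells of dpc16 thus had EGFP less often than those of NP and dpp42. A different set of fibroblast clusters in dpc16 is argued against, because in clusters 2 and 21 the dpc16 share was 0 of 209, with an exact upper limit of 1.75%, below the lower limit of 5.88% in NP, and with cluster 19 added it was 2 of 466, with an upper limit of 1.54%, below 5.59% in NP. Lower depth is argued against by the 4088.5 median UMIs of dpc16 fibroblast-like cells. Free RNA as the whole source of EGFP in dpc16 keratinocyte-like cells is argued against per UMI, because 0 UMIs in endothelial-like cells have an upper limit of 2.69 CPM, below the 4.45 CPM lower limit of the class, but outside clusters 4, 5 and 10 the class stood at 2.67 CPM (1.61 to 4.18), where free RNA and expression cannot be told apart, and the shares at equal depth overlap. The timing and dose of tamoxifen, a wrong label or genotype of the dpc16 mouse, the individual mouse and the stage of pregnancy stay open and were not tested, and any of them may account for the low dpc16 share.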

How the results depend on the processing

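Settings were changed one at a time and chosen before the data were examined, except for 2 added later, the exclusion of the highest doublet scores and the equal weighting of clusters. No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out in turn. Keeping doublets changed nothing, since none had been removed. The cause was not tested for any change below. Of the values of shares under alternatives, 185 stayed within the interval of the reported value and 82 moved. Of list medians, 1065 stayed, 69 moved and 6 reversed, and of log2 ratios of the single genes given in the text, 1612 stayed, 369 moved and 15 reversed. Only a gene past the size rule, or a list median whose interval excludes 0, counts as reversed. The text's 182 gene ratios were chosen after values were seen. Over all 410 that the fixed rule names, 3731 values stayed, 698 moved and 42 reversed. The fibroblast-like share was highest in dpc16 under every setting run, with ranges of 3.96 to 10.0% in NP, 15.8 to 32.2% in dpc16 and 4.35 to 12.9% in dpp42. The order of NP and dpp42 depended on the setting.

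With at most 5% mitochondrial UMIs, fibroblast-like shares were 5.78, 25.5 and 5.14% in NP, dpc16 and dpp42, keratinocyte-like shares 84.4% in NP and 71.7% in dpp42, and blood endothelial-like shares 4.21% in dpc16 and 11.2% in dpp42. The heat shock median for dpp42 over NP was 0.47. Reversed values there were the ribosomal protein median for dpp42 over NP (0.11), and the log2 ratios for dpc16 over NP of Plac8 (-1.70), Cxcl13 (-1.22) and Nr4a2 (1.53), for dpp42 over NP of Mt2 (0.058), Rxfp1 (-1.16) and Hk2 (0.29), and for dpp42 over dpc16 of Bnip3 (-0.62). In dpc16, the fibroblast-like and keratinocyte-like shares were 26.6 and 51.0% with at most 20% mitochondrial UMIs, 27.7 and 51.3% with no filter, and 31.6 and 49.3% at resolution 0.5. At resolution 2, fibroblast-like shares were 10.0, 32.2 and 12.9%, and reversed log2 ratios were those of Apoe (-0.43) and Plin2 (-0.91) for dpc16 over NP and Apoe (-0.054) for dpp42 over NP. With each library clustered alone, the dpc16 fibroblast-like share was 19.2%, keratinocyte-like shares were 73.1% in NP and 47.1% in dpc16, the heat shock median for dpp42 over NP was -0.42, and Plac8 for dpc16 over NP reversed to -2.17. With no clustering, fibroblast-like shares were 3.96, 15.8 and 4.35%, and keratinocyte-like shares 23.5, 20.6 and 19.5%. Without stress and proliferation genes in the clustering, fibroblast-like shares were 5.66, 26.7 and 5.46% and the dpc16 keratinocyte-like share 48.1%, and reversed log2 ratios were those of Klf2 for dpp42 over NP (-0.12) and Bnip3 for dpp42 over dpc16 (-1.32). With cells thinned to 1000 UMIs before clustering, fibroblast-like shares were 5.74, 20.5 and 5.09% and the dpc16 keratinocyte-like share 49.7%. Without the 5% highest doublet scores, the dpc16 keratinocyte-like share was 47.3% and the heat shock median for dpp42 over NP -0.42. With clusters weighted equally, Cxcl13 for dpc16 over NP (-0.34) and Mt2 for dpp42 over NP (0.054) reversed, and Igfbp2 for dpc16 over NP turned from -0.25 to 0.69, which is not counted because its reported ratio is short of the size rule. With all cells of a library in place of the class, which changes the cells measured, the collagen and chemokine medians for dpc16 over NP were 1.82 and 1.10, the latter against a fibroblast-like median of -0.93 whose interval, -1.31 to 0.21, spans 0. Reversed medians there were secretory pathway (0.23) and mitochondrial transcripts (0.16) for dpc16 over NP, chemokines for dpp42 over NP (0.049), and secretory pathway (-0.30) and papillary genes (-0.38) for dpp42 over dpc16.

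Proliferating shares of all kept cells were 10.0% in NP and 7.15% in dpc16 when thinned to 2000 UMIs, 15.3, 14.6 and 14.7% when not thinned, 17.6, 14.8 and 16.7% with 1 gene, and 3.83% in dpc16 with 3 genes. In fibroblast-like cells they were 6.00, 6.92 and 8.93% with 1 gene, and in dpc16 1.85% when thinned to 2000 UMIs and 4.43% when not thinned, so the order of the libraries changed with the setting. Scaling by the median ratio changed the log2 ratios of measured genes by a median of 0.13 for dpc16 over NP and -0.15 for dpp42 over dpc16, and leaving out the most abundant genes by 0.16 and -0.19. The median change per gene was 0.26 and -0.30 at resolution 2, -0.21 and 0.18 with 2 added UMIs, and 0.26 and -0.37 with all cells of the library. No gene or list given here reversed with scaling, but the most abundant genes had no value in the scaling that leaves them out. No list reversed with 2 added UMIs. Reversal of single genes was not checked with added UMIs, so genes with few UMIs stay untested there.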

Other observations

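Of the tests here, 2 on clusters of the chemokine list were written before their result was seen, and those on the fibroblast-like share and on the dissociation response after it. Keratinocyte-like clusters 4 and 9 were chosen after their values were seen, and each held at least 85 cells in every library. Cluster 4, led by Ccl27a, Krt5 and Krt14, is basal-like. In dpc16, the progesterone-metabolising enzyme gene Akr1c18 stood at 102 against 21 CPM of NP (4.88-fold, 2.65 to 9.84) and the serine synthesis gene Phgdh at 261 against 68.1 CPM (3.83-fold, 2.71 to 5.54). Wdr89 stood at 136 against 776 CPM (5.70-fold lower, 4.61 to 7.09). In dpp42, Snai2 stood at 91.7 against 22.7 CPM (4.04-fold, 2.01 to 8.52) and Klf2 at 34.0 against 147 CPM (4.32-fold lower, 2.24 to 9.34). Cluster 9, led by Mt4, Krt1 and Krt10, is differentiated. In dpc16, Stfa3, a stefin A gene with close paralogs and so an uncertain count, stood at 281 against 4.32 CPM (65.1-fold, 27.5 to 202), the water channel gene Aqp3 at 151 against 45.8 CPM, Sema3d at 19.1 against 164 CPM and Skint10 at 25.1 against 189 CPM. The keratin gene Krt16 stood at 15.5 CPM in NP, 61.0 in dpc16 and 61.8 in dpp42, and Sprr1a at 43.4 against 204 CPM in dpp42 and NP. The heat shock list had medians of 0.77 (-0.11 to 1.38, 6 of 11 higher) in cluster 4 and 0.72 (0.24 to 1.35, 7 of 11 higher) in cluster 9 for dpc16 over NP. The interval of cluster 4 spans 0. The immediate early list was lower in dpp42 than in NP in both, with medians of -0.51 (6 of 18 lower) and -0.45 (6 of 19 lower). Ribosomal protein genes had a median of 0.52 in cluster 9 for dpc16 over NP, with 27 higher and 4 lower of 78.

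The fibroblast-like share was higher in dpc16 than in the other libraries. Fewer keratinocyte-like cells in the suspension would, acting alone, raise every other class alike. The blood endothelial share ratio of dpc16 over NP was 1.10 (0.770 to 1.61) and that of fibroblast-like cells 3.83 (3.12 to 4.74). This argues against fewer keratinocyte-like cells as the whole cause only if the classes compared did not change themselves. The blood endothelial share did change in another comparison, at 2.59 (1.77 to 3.84) for dpp42 over NP. Ratios of T, NK and innate lymphoid-like (1.06, 0.460 to 2.73), hair follicle dermal-like (0.912, 0.455 to 1.95) and Schwann-like cells (0.647, 0.219 to 2.13) lay below the fibroblast-like ratio too. Those of lymphatic endothelial-like (2.62, 1.62 to 4.48) and mural-like cells (2.05, 0.784 to 6.77) overlap it, as does that of the mixed macrophage-like class (4.18, 2.32 to 8.27). Non-epithelial cells together, fibroblast-like cells included, went from 15.98% of kept cells in NP to 45.02% in dpc16. Among them the fibroblast-like share went from 48.5% (41.5 to 55.6%) to 65.9% (63.6 to 68.2%). How much of the rise goes with fewer keratinocyte-like cells therefore stays open. Depth is argued against as the whole cause, because with cells thinned to 1000 UMIs the dpc16 share was 20.5%. The NP share under the same thinning was 5.74%, with an upper limit of 7.15%. More fibroblasts in the dermis at gestation day 16, a different release of cells by trypsin and pipetting, a deeper layer of skin and the individual mouse stay open. Of these only the skin layer was tried, by cluster sizes, and set aside, because the genes that define those clusters differ between the libraries.

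The chemokine list was lower than NP in fibroblast-like cells of dpc16 (median -0.93, interval -1.31 to 0.21) and dpp42 (-0.70, interval -2.68 to -0.07). With clusters 2, 19 and 21 weighted equally, the medians were -0.37 and -0.10, past the bounds set in advance for an effect of different clusters. Since Ccl2 and Ccl7 of the list lead cluster 2, this weighting draws on the pattern itself, and a reading made after the values were seen is that different clusters and lower expression cannot be told apart. In keratinocyte-like clusters 4 and 9, outside the fibroblast-like class, the list medians for dpp42 over NP were -0.58 (-1.93 to 0.88, 5 measured) and -0.80 (-1.43 to -0.39, 4 measured). With so few members, these brackets run from the lowest to the highest member and are not intervals of the median. For dpc16 over NP the list medians were 0.50 (-0.26 to 1.38) and 0.58 (-1.32 to 1.19). So few genes of another class do not settle the question. A weaker response to dissociation is argued against for dpc16, where the immediate early median was 0.035 (-0.20 to 0.34), and cannot be told apart for dpp42, where it was -0.51 (-0.74 to -0.05). There it was lower in keratinocyte-like clusters 4 and 9 too, but higher in 41 NP and 89 dpp42 blood endothelial-like cells, at 0.35 (0.06 to 0.48), so the classes do not move alike. The stage and the individual mouse were not tested.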
